A study of Homo sapiens with 13 samples.

How the data were processed

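RNA sequencing was carried out on 13 libraries of BeWo, a human choriocarcinoma cell line with trophoblast properties, grown in medium with 10% fetal calf serum. Per the labels' protocols, total RNA was isolated with a Promega kit and libraries were made with a directional (strand-keeping) MGIEasy kit. Groups were taken from the sample titles: 3 untreated control libraries, 3 exposed to sulfamethoxazole (SMZ), 3 to trimethoprim (TMP), 3 to co-trimoxazole (CTX) and 1 to dimethyl sulfoxide (DMSO). The labels do not say whether the replicates of a group were separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

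The deposited raw table holds whole-number counts per Ensembl gene and library, made by the authors, with 62699 genes and no normalization. The submitters' processing notes name HISAT2, featureCounts, Salmon and DESeq2 and the builds hg38 and GRCh38, without saying which tool did what. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. All 62699 gene identifiers were found in the table of gene names, where 20357 have no name other than the identifier. A GENCODE annotation on GRCh38 held 58206 of them and gave the positions and the transcript GC content and length used here. Genes lying at least 95% within exons of a gene on the opposite strand had a median count density of 0.0272 of their partner's (295 genes), against 0.344 for such genes on the same strand (307 genes). Reads of genes that share exons on the same strand, and of near-identical copies such as histones, GH2 and CSH1, or CGB5, may still be split between genes, so these values are uncertain.

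The deposited normalized table gives a signal per gene symbol that the authors had scaled by 1 factor per library, as the values show. Within each library 100% of its values were whole multiples of 1 read, within 0.01 reads, so reads could be recovered. The recovered reads came to a median of 1.91 to 1.92 times the raw counts per gene, and 26 symbols had turned into dates. It therefore came from another counting run, and 17772 of its 25284 symbols were found among the raw table's. The count test was repeated on these reads as an alternative chosen after the data were seen, and called 8574 genes for SMZ, 4336 for TMP and 749 for CTX against control.

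Totals ran from 34372752 to 61451951 counts per library. No gene took more than 1.44% of a library. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.66 to 13.3 over genes, so each library was counted as its own sample. Scaling factors by the trimmed mean of M values (TMM) ran from 0.955 to 0.969 in control and from 1.06 to 1.08 in SMZ libraries.

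Genes with enough counts were kept with edgeR's filter by group, which left 21392. All 13 libraries entered 1 fit with a coefficient per group, and each pair of groups was compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. The common biological coefficient of variation was 5.89%. Log2 fold changes are given ± their standard error, and levels as TMM-scaled CPM, counts scaled to library size, ± SD over 3 libraries. DMSO has 1 library, so its comparisons borrow the spread of the replicated groups, assume that the lone library varies like them, and compare that library, not the condition.

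Lists of genes for 41 pathways, cell types and processes were written before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 41 lists. Members past the gene test were counted over all genes tested and adjusted over the list alone. Lists can share members, such as MYC among immediate early, ribosome biogenesis and Wnt genes, so their results are not independent. The call of a list was repeated with a correlation estimated from the data. Across the 10 comparisons, 1 list call held with the estimated correlation, that of the p53 targets in CTX against TMP. Camera called 14 of the 41 lists for SMZ, 18 for TMP, 18 for CTX and 21 for DMSO against control. Which of these lists are described was chosen after their results were seen.

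Genes to name were set by a rule before the data were examined. For each drug against control it took the 6 rising and 6 falling genes with the largest fold change among called genes with a mean of at least 1 CPM, no overlap between the libraries of both groups, and no placeholder, antisense or pseudogene-type symbol. For other comparisons it took 3 and 3. The largest or furthest changes named are those among genes that met this rule. From each list described it took up to 4 members with the smallest adjusted p, and 8 genes of folate handling, placental hormones and drug efflux were given whatever their result. Among the genes taken, GGTLC5P carries a pseudogene-type name that the rule's pattern let through.

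The tests were first tried on simulated counts. Changed genes were drawn from those with a mean of at least 1 CPM, with as many raised as lowered. They were far fewer than the 9229 genes called for SMZ against control. Recovery in genes of lower counts, or with so many genes changed, was therefore not measured. For SMZ against control, edgeR recovered 38% of genes changed 1.2-fold, 74% at 1.3-fold, 80% at 1.5-fold and 96% at 2-fold, of 50 genes each, with 12 false calls among 156. For DMSO against control, it recovered 10%, 28%, 80% and 92% of them, with 7 false calls among 112. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, other scaling factors, no or a stricter low-count filter, a fold threshold, fits of only the groups compared, the replicate number as a block, and each replicate left out in turn. Where groups share replicate numbers, deviations from the group means were correlated across genes between libraries, with a number taken to pair them when all 3 same-numbered pairs exceeded 0.1. Control and TMP met this (0.160 to 0.283, against -0.266 to 0.0484 for the 6 other pairs), from the data alone, since the labels do not say what a number marks. The deviations of a group's 3 libraries sum to 0, so positive same-numbered pairs by themselves push the other pairs down. Control and TMP were the only groups to meet the rule of all those screened, so a match by chance is not excluded. A fit of these 6 libraries with the number as a block, added after the data were seen, called 5798 genes. The same 6 libraries without the block gave 4636, and the fit of all 13 libraries 4625. Comparisons against shared control libraries were set beside 20 simulations of unchanged groups.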

Results

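Gene expression was measured by RNA sequencing in BeWo cells, a human choriocarcinoma line used as a model of placental trophoblast, after 24 h with antibiotics given together as co-trimoxazole. SMZ, which blocks folate synthesis in bacteria, was used at 200 µg/ml. TMP, an inhibitor of bacterial dihydrofolate reductase, and CTX, the combination, were each used at 50 µg/ml. The labels do not give how much of each drug the 50 µg/ml of CTX held, nor the vehicle of the drug wells. The control libraries came from untreated cells (n = 3), and 1 library came from cells in 1% DMSO. Depth was 44840182 to 51101741 counts in the control libraries, 34372752 to 50882830 with SMZ, 46031831 to 61451951 with TMP, 40274599 to 58777578 with CTX and 54815255 with DMSO.

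The libraries lay apart by group along the first principal component of log2 CPM, which held 30.2% of the variance, with control at one end, SMZ at the other, and CTX, TMP and DMSO between them. TMP lay apart from the others along the second, with 12.6%.

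**Figure D1:**
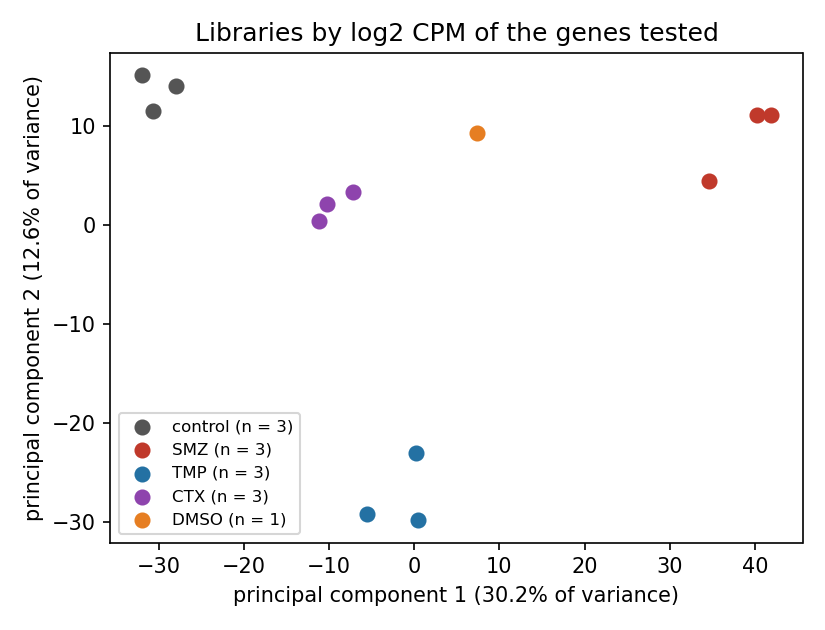
Principal component 1 (x axis) and 2 (y axis) of log2 CPM of the genes tested, 1 point per library and coloured by group, with 30.2% and 12.6% of the variance on the axes. The 3 libraries of each replicated group lie together, and the DMSO library lies between CTX and SMZ on the first component.

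The first question was what differed between the SMZ wells, whose vehicle is not given, and untreated cells. Genes of the integrated stress response, the programme that ATF4 drives when amino acids or protein folding fail, were lower with SMZ: 35 of 39 measured targets fell and none rose (36 fell adjusted over the list alone). DDIT4, an inhibitor of mTORC1 signalling (chromosome 10, 72273920 to 72276036), went from 503 ± 19.1 CPM in control to 241 ± 13.9 CPM, a log2 fold change of -1.06 ± 0.054, adjusted p = 4.6e-11 (edgeR, n = 3 against 3). The stress cytokine GDF15 (-1.15 ± 0.063), the transcription factor ATF3 (-0.91 ± 0.057) and PPP1R15A, which helps to reverse the phosphorylation of eIF2α (-0.90 ± 0.055), fell too. Of 36 hypoxia and glycolysis genes 33 fell and none rose (33 lower and 1 higher adjusted over the list alone). Among them were the glucose transporter SLC2A1 (-0.93 ± 0.064), hexokinase HK2 (-1.04 ± 0.071), NDRG1 (-1.06 ± 0.063) and the vasodilator peptide ADM (-1.34 ± 0.092). Both lists ranked lower than other genes, the ATF4 targets with a camera adjusted p = 4.4e-21, and adjusted p = 0.14 with an estimated correlation. For hypoxia and glycolysis the values were a camera adjusted p = 4.2e-13, and adjusted p = 0.14 with an estimated correlation.

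Placental marker lists were lower with SMZ as well. Of 24 genes of the syncytiotrophoblast, the fused hormone-making layer, 15 fell and 1 rose (1 higher and 16 lower adjusted over the list alone), with camera adjusted p = 2.8e-05, and adjusted p = 0.14 with an estimated correlation. Placental growth hormone GH2 (chromosome 17, 63880215 to 63881935) dropped 2.60-fold, from 47.0 ± 1.69 to 18.1 ± 0.665 CPM (-1.38 ± 0.057, adjusted p = 4.5e-12, edgeR), though reads may be shared with its near-identical copies. GCM1, the transcription factor of trophoblast fusion, changed by -0.73 ± 0.061, and CGA, the common subunit of glycoprotein hormones, by -0.41 ± 0.11, adjusted p = 0.0067 (edgeR). Without SMZ 2 the CGA change was -0.25, still past the test (adjusted p = 0.040). CGB5, a hormone subunit with a mean under 1 CPM in both groups, stood at 0.051 ± 0.22, adjusted p = 0.88. Among 16 extravillous trophoblast markers 10 fell and 2 rose, including SERPINE1 at -1.11 ± 0.048 and the integrin ITGA5 at -0.69 ± 0.057. The extravillous trophoblast list had 2 higher and 11 lower adjusted over the list alone, with camera adjusted p = 1.7e-04, and adjusted p = 0.20 with an estimated correlation. Of 22 cytotrophoblast genes 14 fell, such as TP63 (-0.76 ± 0.056) and EGFR (-0.82 ± 0.061), and 4 rose, such as PEG10 (0.69 ± 0.058). That list had 4 higher and 14 lower adjusted over the list alone, with camera adjusted p = 0.0017, and adjusted p = 0.26 with an estimated correlation.

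Genes of growth and inflammation followed. Immediate early genes fell in 16 of 26 cases and rose in 4, with FOSL2 at -1.01 ± 0.055 and CCN1 at -0.93 ± 0.075. The immediate early list had 5 higher and 17 lower adjusted over the list alone, with camera adjusted p = 3.8e-05, and adjusted p = 0.14 with an estimated correlation. Ribosome biogenesis genes fell in 16 of 27 cases and rose in 2, with MYC at -0.70 ± 0.083. The ribosome biogenesis list had 2 higher and 16 lower adjusted over the list alone, with camera adjusted p = 4.4e-05, and adjusted p = 0.14 with an estimated correlation. IL6, an inflammatory cytokine (chromosome 7, 22725884 to 22732002), fell 4.79-fold to 1.03 ± 0.272 CPM (-2.26 ± 0.16, adjusted p = 2.0e-09, edgeR). With TNFAIP3 (-0.84 ± 0.075) it was among 9 of 15 NF-kB genes that fell, while 2 rose, including SOD2 (0.60 ± 0.066). For the NF-kB list the counts were 2 higher and 9 lower adjusted over the list alone, with camera adjusted p = 0.0027, and adjusted p = 0.14 with an estimated correlation. Unfolded protein response genes fell in 13 of 24 cases and rose in 1, with XBP1 at -0.61 ± 0.049. The unfolded protein response list had 1 higher and 14 lower adjusted over the list alone, with camera adjusted p = 2.8e-05, and adjusted p = 0.24 with an estimated correlation.

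Folate genes moved both ways with SMZ: of 36 measured, 15 fell and 9 rose (10 higher and 15 lower adjusted over the list alone), and the list did not rank apart from other genes (camera adjusted p = 0.23, and adjusted p = 0.39 with an estimated correlation). MTHFD1L (-0.90 ± 0.055) and SHMT2 (-0.53 ± 0.049), mitochondrial enzymes of one-carbon metabolism, fell. GGH, which trims folate polyglutamates, rose by 0.50 ± 0.058, and DHFR, the human dihydrofolate reductase (chromosome 5, 80626228 to 80654983), by 0.34 ± 0.060, adjusted p = 1.4e-04 (edgeR). The reduced folate carrier SLC19A1 fell (-0.34 ± 0.067, adjusted p = 3.9e-04, edgeR). Folate receptor FOLR1 (0.074 ± 0.056, adjusted p = 0.31), the transporter SLC46A1 (0.025 ± 0.057, adjusted p = 0.76) and the efflux pump ABCG2 (0.018 ± 0.057, adjusted p = 0.83) did not pass the edgeR test. ABCB1, another efflux pump, had 8 counts over 13 libraries, 0 to 2 in each, and was not tested. Of 24 nutrient transporters 15 fell, with the amino acid carrier SLC7A5 at -0.96 ± 0.065, and 6 rose, with SLC7A6 at 0.80 ± 0.056. The nutrient transporter list had 6 higher and 15 lower adjusted over the list alone, with camera adjusted p = 0.0072, and adjusted p = 0.28 with an estimated correlation. Of 6 targets of the aryl hydrocarbon receptor 5 fell, CYP1A1 by -1.55 ± 0.10 and AHRR by -0.52 ± 0.048, and NQO1 rose by 1.08 ± 0.078. The aryl hydrocarbon receptor list had 1 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.0072, and adjusted p = 0.15 with an estimated correlation.

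In all, edgeR called 9229 of 21392 genes for SMZ against control, 4708 higher and 4521 lower, of which 1148 changed at least 2-fold, 681 higher and 467 lower. Which direction held more genes depended on the settings, with 4351 higher and 4857 lower with other scaling factors, 3596 and 4485 with DESeq2, and 4477 and 4653 without a low-count filter. The largest falls were in muscle actin ACTA1 (chromosome 1, 229431245 to 229434098; -2.48 ± 0.17), the lipid hydroxylase CYP4F22 (-2.43 ± 0.17), ENDOU (-2.38 ± 0.19), ADGRF2 (-2.31 ± 0.16), IL6 and SPRY4, an inhibitor of receptor tyrosine kinase signalling (-2.25 ± 0.093). All of these were also lower in the DMSO library than in every control library. The labels do not give the vehicle of the SMZ wells, so a vehicle part in these falls cannot be told apart from SMZ. The largest rises were in histone H2BC6 (1.98 ± 0.17), SLAIN1 (1.97 ± 0.17), SPIRE1 (1.94 ± 0.20), ANKRD34A (1.90 ± 0.20), NELFE and WNT9A (1.80 ± 0.16). NELFE lies in the major histocompatibility complex and varied widely between SMZ libraries (7.40 ± 7.96 CPM, log2 fold change 1.88 ± 0.63, adjusted p = 0.022, edgeR). Its call was lost without control 1, control 3 or SMZ 2 (log2 fold change 0.49 to 1.88, adjusted p = 0.51 at most), and without SMZ 2 its log2 fold change was 0.49. It was also lost with DESeq2 (adjusted p = 0.0528) and limma-voom (adjusted p = 0.10). Markers of other cell types moved with SMZ too. Of 6 immune markers 4 fell, with CSF1R at 601 ± 20.6 CPM in control and -0.49 ± 0.047 with SMZ. The immune list had 0 higher and 4 lower adjusted over the list alone, with camera adjusted p = 0.0097, and adjusted p = 0.14 with an estimated correlation. Without a low-count filter the immune list was not called for SMZ (adjusted p = 0.15). Of 5 endothelial markers 2 fell, CDH5 (-0.74 ± 0.053) and VWF (-0.94 ± 0.10), with 0 higher and 2 lower adjusted over the list alone, a list median of 0.085 and a mean of -0.22 (camera adjusted p = 0.27, and adjusted p = 0.55 with an estimated correlation). Of 9 stromal markers 3 rose and 2 fell (3 higher and 2 lower adjusted over the list alone), with a median of 0.16 and a mean of 0.14 against a camera direction of down (camera adjusted p = 0.98, and adjusted p = 0.98 with an estimated correlation).

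TMP moved many of the ATF4 targets the other way, but not all. With TMP 21 of 39 rose and 3 fell (24 higher and 4 lower adjusted over the list alone). Asparagine synthetase ASNS (chromosome 7, 97852118 to 97872542) rose 2.02-fold, from 54.4 ± 11.8 to 110.0 ± 24.8 CPM (1.01 ± 0.14, adjusted p = 5.1e-05, edgeR, n = 3 against 3), with 44.6% of its exonic bases shared with another gene on its strand. ASNS was among the 1% of genes with the largest spread between replicates, with control libraries at 45.9 to 67.9 CPM and TMP libraries at 88.1 to 136.9 CPM. The serine synthesis enzyme PSAT1 (0.70 ± 0.10) and the pseudokinase TRIB3 (0.62 ± 0.087) rose, while GDF15 fell (-0.74 ± 0.062). ATF3 and PPP1R15A, which fell with SMZ, were also below every control library with TMP. ATF3 was at 72.68 to 78.74 CPM against 84.5 to 92.47 in control, and PPP1R15A at 89.84 to 99.3 against 105.41 to 115.99. DDIT4, at 507.64 to 561.83 CPM with TMP, overlapped the 488.03 to 524.59 CPM of control. The list ranked higher than other genes (camera adjusted p = 2.2e-06, and adjusted p = 0.41 with an estimated correlation). Of 33 replication-dependent histone genes 12 rose and none fell, among them H2BC5 (1.01 ± 0.10), H2AC6 (0.76 ± 0.093) and H2BC6 (1.26 ± 0.17). The histone list had 13 higher and 0 lower adjusted over the list alone, with camera adjusted p = 2.2e-06, and adjusted p = 0.12 with an estimated correlation. H3C4 rose by 1.83 ± 0.21, with 100% of its exonic bases shared with another gene, and histone copies can share reads.

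**Figure D2:**
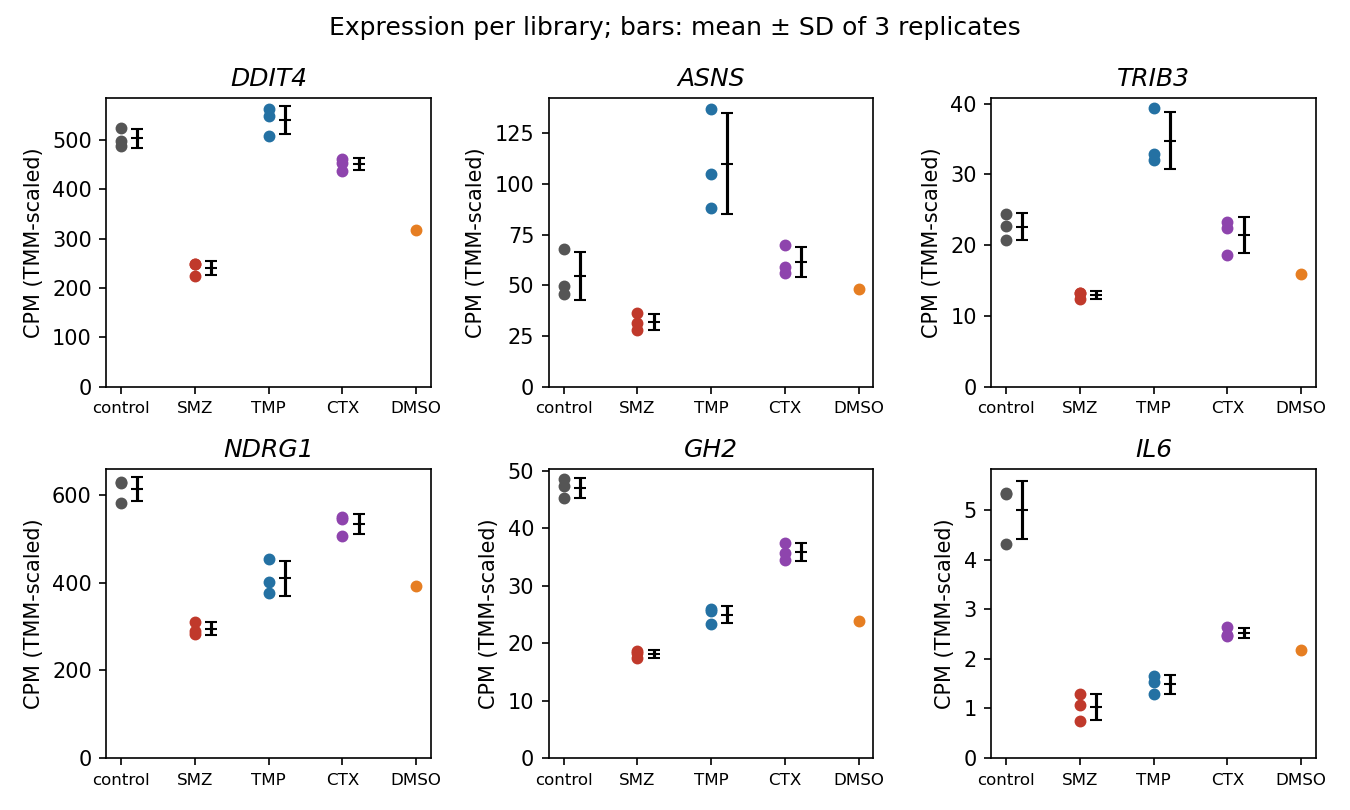
TMM-scaled CPM (y axis) of DDIT4, ASNS, TRIB3, NDRG1, GH2 and IL6 in each library by group (x axis), with bars for the mean ± SD of 3 replicates and 1 point for DMSO. ASNS averaged 110.0 CPM with TMP against 54.4 in control, and GH2 18.1 CPM with SMZ against 47.0.

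Other groups were lower with TMP. Hypoxia and glycolysis genes fell in 15 of 36 cases and none rose, with NDRG1 at -0.58 ± 0.063 and the kinase PDK1 at -0.40 ± 0.052. The hypoxia and glycolysis list had 1 higher and 19 lower adjusted over the list alone, with camera adjusted p = 1.3e-05, and adjusted p = 0.29 with an estimated correlation. Of 30 p53 targets 14 fell and 1 rose, including the cell cycle inhibitor CDKN1A (-0.26 ± 0.046), the repair gene DDB2 (-0.31 ± 0.043) and PHLDA3 (-0.35 ± 0.046). The p53 target list had 2 higher and 17 lower adjusted over the list alone, with camera adjusted p = 2.2e-05, and adjusted p = 0.091 with an estimated correlation. NF-kB genes fell in 7 of 15 cases and rose in 1, with IL6 at -1.74 ± 0.14, TNFAIP2 at -0.80 ± 0.055 and LIF at -0.60 ± 0.060. The NF-kB list had 1 higher and 7 lower adjusted over the list alone, with camera adjusted p = 1.8e-04, and adjusted p = 0.091 with an estimated correlation. Of 24 syncytiotrophoblast genes 11 fell and 1 rose, with GH2 at -0.92 ± 0.055, placental lactogen CSH1 at -1.01 ± 0.14 and CGA at -0.54 ± 0.11, adjusted p = 0.0021 (edgeR). The syncytiotrophoblast list had 2 higher and 11 lower adjusted over the list alone, with camera adjusted p = 3.0e-04, and adjusted p = 0.20 with an estimated correlation. CGB5 stood at 0.15 ± 0.21, adjusted p = 0.68 (edgeR). Extravillous markers fell in 7 of 16 cases and none rose, with SERPINE1 at -0.73 ± 0.047. Within the extravillous trophoblast list there were 0 higher and 7 lower adjusted over the list alone, with camera adjusted p = 3.4e-04, and adjusted p = 0.21 with an estimated correlation. Of 6 aryl hydrocarbon receptor targets 4 fell, with CYP1A1 at -0.72 ± 0.092, and NQO1 rose (0.36 ± 0.079; 1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0045, and adjusted p = 0.15 with an estimated correlation).

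Of 36 folate genes 9 rose and 3 fell with TMP (9 higher and 3 lower adjusted over the list alone), and the list did not rank apart (camera adjusted p = 0.38, and adjusted p = 0.50 with an estimated correlation). MTHFD2 (0.68 ± 0.10) and ALDH1L2 (0.90 ± 0.13), mitochondrial folate enzymes, rose, as did MTHFR (0.49 ± 0.083), and the transporter ABCC5 fell (-0.30 ± 0.047). The TMP target's human form, DHFR, stood at -0.032 ± 0.060, adjusted p = 0.77, FOLR1 at 0.020 ± 0.056, adjusted p = 0.85, SLC19A1 at -0.10 ± 0.066, adjusted p = 0.30 and SLC46A1 at 0.10 ± 0.057, adjusted p = 0.24, none past the edgeR threshold. ABCG2 fell (-0.24 ± 0.057, adjusted p = 0.0045, edgeR). In all, edgeR called 4625 genes, 2306 higher and 2319 lower. Of the 425 that changed at least 2-fold, 87 were higher and 338 lower. With other scaling factors 2017 were higher and 2524 lower, with DESeq2 1771 and 2327, and with limma-voom 2880 and 2833. The RNA-editing enzyme ADARB1 rose 2.34-fold (1.23 ± 0.053), and TRIM36 (1.06 ± 0.16), the NAD synthesis enzyme NMNAT1 (1.04 ± 0.12) and neuronal tubulin TUBB3 (1.05 ± 0.10, 35.8% of exonic bases shared on its strand) rose. The largest falls were in CYP1A2 (-2.26 ± 0.29), ATF6B, endothelin EDN2 (-1.77 ± 0.14), CYP4F2 (-1.75 ± 0.19), IL6 and the peptidase MME (-1.74 ± 0.25). All of these were also lower in the DMSO library than in every control library. The vehicle of the TMP wells is not given either, so a vehicle part in these falls cannot be told apart from TMP. NELFE (2.26 ± 0.62) and ATF6B (-2.16 ± 0.57) lie in the major histocompatibility complex and had some of the largest spreads between replicates. The call of NELFE was lost without control 3 or TMP 3 (log2 fold change 1.42 to 2.12, adjusted p = 0.11 at most), with a log2 fold change of 1.42 without TMP 3, and that of ATF6B without control 2 (log2 fold change -1.46, adjusted p = 0.10). Of other cell types' markers, 4 of 6 immune genes fell, with ITGAM at -1.02 ± 0.050. Within the immune list there were 0 higher and 4 lower adjusted over the list alone, with camera adjusted p = 7.4e-04, and adjusted p = 0.091 with an estimated correlation. CDH5 (-0.94 ± 0.053) and VWF (-0.93 ± 0.093) were the 2 of 5 endothelial genes that fell, and 3 of 9 stromal genes fell, with COL6A3 at -0.39 ± 0.070. The stromal gene COL6A1 (-0.16 ± 0.055) lost its call without control 1, control 2, TMP 1 or TMP 3 (log2 fold change -0.13 to -0.18, adjusted p = 0.16 at most). The endothelial list had 0 higher and 2 lower adjusted over the list alone, with camera adjusted p = 0.0081, and adjusted p = 0.15 with an estimated correlation. The stromal list had 0 higher and 3 lower adjusted over the list alone, with camera adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation.

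Fewer genes were called for CTX than for SMZ or TMP. Against control the scavenger receptor OLR1 (chromosome 12, 10158301 to 10172138) fell 1.91-fold (-0.93 ± 0.079, adjusted p = 1.1e-05, edgeR, n = 3 against 3), IL6 fell 1.98-fold (-0.98 ± 0.14) and the splicing factor PRPF31 2.10-fold (-1.07 ± 0.17). Of 22 cytotrophoblast genes 7 fell and none rose, with keratin KRT7 at -0.26 ± 0.045 and the integrin ITGB4 at -0.24 ± 0.045. ITGA6 (-0.21 ± 0.046) lost its call without control 1 or CTX 2 (log2 fold change -0.21, adjusted p = 0.058 at most), and TFAP2A (-0.28 ± 0.063) without control 1, CTX 1 or CTX 3 (log2 fold change -0.26 to -0.27, adjusted p = 0.080 at most). The cytotrophoblast list had 1 higher and 11 lower adjusted over the list alone, with camera adjusted p = 7.3e-06, and adjusted p = 0.16 with an estimated correlation. Of 26 immediate early genes 3 fell and none rose, with CCN1 at -0.45 ± 0.073 and FOSL2 at -0.33 ± 0.054. Within the immediate early list there were 1 higher and 7 lower adjusted over the list alone, with camera adjusted p = 7.3e-06, and adjusted p = 0.15 with an estimated correlation. The third immediate early gene, MYC (-0.31 ± 0.080), lost its call without control 1, control 2, control 3, CTX 1 or CTX 3 (log2 fold change -0.26 to -0.35, adjusted p = 0.14 at most). Hypoxia and glycolysis genes fell in 2 of 36 cases, ADM (-0.39 ± 0.089) and PDK1 (-0.20 ± 0.051), and none rose. Within the hypoxia and glycolysis list there were 0 higher and 7 lower adjusted over the list alone, with camera adjusted p = 7.3e-06, and adjusted p = 0.29 with an estimated correlation. The call of ADM was lost without control 1, control 3 or CTX 3 (log2 fold change -0.33 to -0.39, adjusted p = 0.072 at most) and that of PDK1 without control 1, control 3, CTX 2 or CTX 3 (log2 fold change -0.18 to -0.21, adjusted p = 0.12 at most). Of 39 ATF4 targets 4 fell and none rose. The ATF4 target list had 0 higher and 8 lower adjusted over the list alone, with camera adjusted p = 3.5e-04, and adjusted p = 0.50 with an estimated correlation. The ATF4 targets that fell included PPP1R15A (-0.30 ± 0.054) and GDF15 (-0.34 ± 0.062), and the list call was lost without control 3 (adjusted p = 0.15). SLC3A2 (-0.25 ± 0.054) lost its call without control 3 or CTX 1 (log2 fold change -0.22 to -0.23, adjusted p = 0.064 at most), and NUPR1 (-0.29 ± 0.071) without control 2, control 3, CTX 1 or CTX 2 (log2 fold change -0.23 to -0.31, adjusted p = 0.12 at most).

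The p53 list ranked higher with CTX (camera adjusted p = 0.031, and adjusted p = 0.29 with an estimated correlation) with a median of 0.059, yet the 1 member of 30 that passed, GADD45A, was lower (-0.20 ± 0.053; 4 higher and 1 lower adjusted over the list alone). The list call was lost without control 1, control 2, CTX 2 or CTX 3 (adjusted p = 0.18 at most), with other scaling factors (adjusted p = 0.054) and with a stricter filter (adjusted p = 0.0511). The call of GADD45A was lost without control 2, control 3, CTX 1, CTX 2 or CTX 3 (log2 fold change -0.18 to -0.22, adjusted p = 0.13 at most). Of 36 folate genes 1 rose, GGH (0.22 ± 0.058), and 1 fell, MTHFD1L (-0.26 ± 0.054), with 1 higher and 1 lower adjusted over the list alone. That list had a median of -0.0046, a mean of 0.015 and a camera direction of down (camera adjusted p = 0.88, and adjusted p = 0.90 with an estimated correlation). GGH lost its call without any 1 of the 6 libraries (log2 fold change 0.18 to 0.24, adjusted p = 0.19 at most), with other scaling factors (adjusted p = 0.054) and in the fit without DMSO (adjusted p = 0.0525). MTHFD1L lost its call without control 3 or CTX 1 (log2 fold change -0.20 to -0.23, adjusted p = 0.0519 at most). None of DHFR (0.047 ± 0.060), SLC19A1 (-0.090 ± 0.067), SLC46A1 (0.047 ± 0.057), FOLR1 (-0.15 ± 0.057), CGA (-0.21 ± 0.11), CGB5 (0.22 ± 0.21) and ABCG2 (-0.061 ± 0.057) passed the edgeR test. A fit of only the CTX and control libraries did call FOLR1 (adjusted p = 0.0478, against up to 0.36 under the other alternatives). CYP1A1 fell (-0.54 ± 0.092), TNFAIP2 fell (-0.27 ± 0.055) and NQO1 rose (0.40 ± 0.080) among 6 aryl hydrocarbon receptor targets. Within the aryl hydrocarbon receptor list there were 1 higher and 3 lower adjusted over the list alone, with camera adjusted p = 0.029, and adjusted p = 0.27 with an estimated correlation. The call of NQO1 was lost without control 1 (log2 fold change 0.32, adjusted p = 0.059), and that of the list without control 3 (adjusted p = 0.0553), without a filter (adjusted p = 0.25) and with a stricter one (adjusted p = 0.058).

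In all, edgeR called 750 genes for CTX against control, 217 higher and 533 lower, and 21 changed at least 2-fold, 8 higher and 13 lower. The count of 750 was smaller in fits with 1 library fewer: 335 without control 1, 476 without control 2, 411 without control 3, 388 without CTX 1 and 413 without CTX 2. It was also 1179 without a low-count filter and 1436 with limma-voom. Calls of the largest rises were lost in fits with 1 library fewer, where the folds stayed close to those of the full fit. ZNF90 and ERMARD were among the 1% of genes with the largest spread between replicates. ZNF90 (2.29 ± 0.52) lost its call without control 1, control 2 or CTX 1 (log2 fold change 2.04 to 2.21, adjusted p = 0.081 at most), ERMARD (1.24 ± 0.34) without any 1 of the 6 libraries (log2 fold change 1.12 to 1.41, adjusted p = 0.16 at most), and MFSD4A (0.68 ± 0.16) without control 1, control 2, CTX 2 or CTX 3 (log2 fold change 0.58 to 0.67, adjusted p = 0.13 at most). ERMARD also lost its call with DESeq2 (adjusted p = 0.068) and a stricter filter (adjusted p = 0.0501). With 1 library fewer the calls were also lost of MYBL1 (0.67 ± 0.14) without control 3 or CTX 1 (log2 fold change 0.57 to 0.61, adjusted p = 0.0542 at most), ZC2HC1A (0.60 ± 0.13) without control 1, CTX 1 or CTX 2 (log2 fold change 0.52 to 0.54, adjusted p = 0.072 at most) and PHLPP2 (0.60 ± 0.13) without control 1 (log2 fold change 0.58, adjusted p = 0.061). Among the largest falls, ANKRD2 (-0.99 ± 0.20) lost its call without CTX 1 (log2 fold change -0.87, adjusted p = 0.062), MME (-0.96 ± 0.24) without control 1, CTX 2 or CTX 3 (log2 fold change -0.69 to -0.82, adjusted p = 0.17 at most) and GGTLC5P (-0.96 ± 0.19) without CTX 2 (log2 fold change -0.83, adjusted p = 0.0501). Of the 40 called genes named by rule for CTX, 14 held with each of the 6 libraries left out in turn, among them OLR1, IL6, PRPF31, KRT7, ITGB4, CCN1, FOSL2, PPP1R15A, GDF15 and CYP1A1. Each of these genes was also lower in the DMSO library than in every control library. OLR1 was at 8.52 CPM in DMSO and 7.39 to 7.98 CPM with CTX. GDF15 was at 130.57 CPM in DMSO and 182.92 to 192.85 CPM with CTX. The labels do not give the vehicle of the CTX wells, so these falls cannot be told apart from a vehicle effect.

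Immune markers fell in 2 of 6 cases with CTX, ITGAM at -0.40 ± 0.048 and CD68 at -0.44 ± 0.10, the second lost without control 1, control 2, CTX 1 or CTX 2 (log2 fold change -0.41 to -0.48, adjusted p = 0.095 at most) and without a low-count filter (adjusted p = 0.0504). CD68 shares 81.7% of its exonic bases with another gene on its strand, so its values, also those given for DMSO, are uncertain. The immune list had 0 higher and 3 lower adjusted over the list alone, with camera adjusted p = 0.0010, and adjusted p = 0.15 with an estimated correlation. Of 5 endothelial markers 2 fell, CDH5 (-0.30 ± 0.053) and VWF (-0.44 ± 0.091), with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.15 with an estimated correlation). VWF lost its call without control 1 (log2 fold change -0.37, adjusted p = 0.068). COL6A3 (-0.28 ± 0.070) was the only one of 9 stromal markers to fall, and lost its call without control 1, control 2, CTX 2 or CTX 3 (log2 fold change -0.24 to -0.29, adjusted p = 0.14 at most). Within the stromal list there were 0 higher and 1 lower adjusted over the list alone, with camera adjusted p = 0.029, and adjusted p = 0.27 with an estimated correlation. The stromal list call was lost without control 1 or CTX 2 (adjusted p = 0.060 at most) and without a low-count filter (adjusted p = 0.080).

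**Figure D3:**
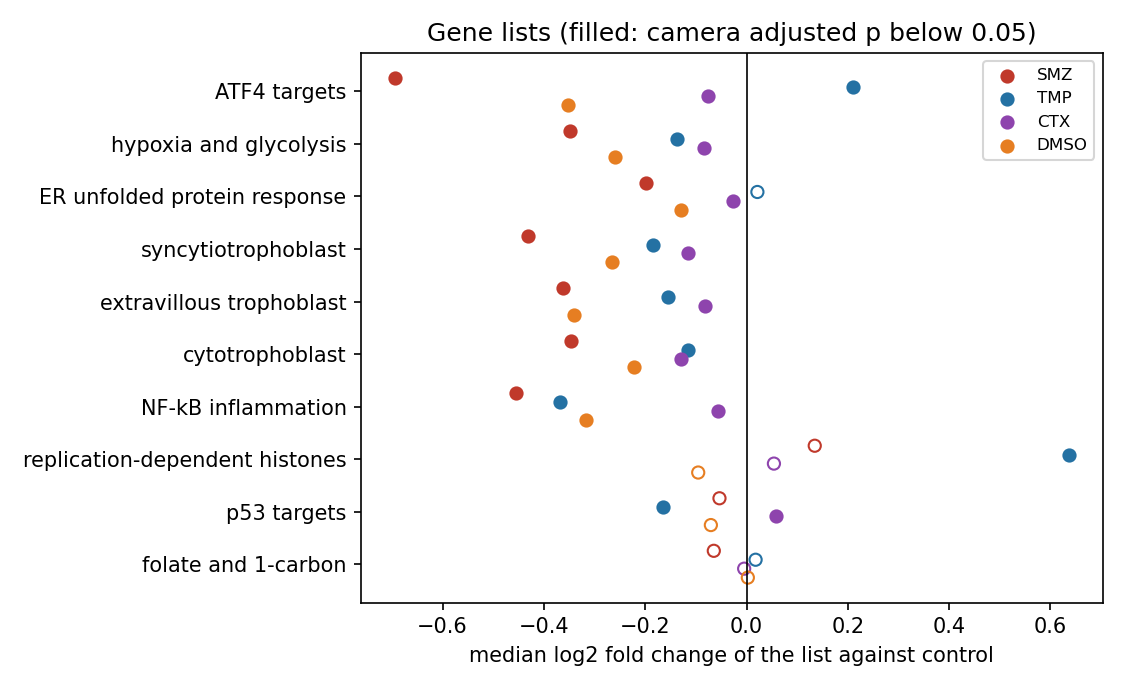
Median log2 fold change against control (x axis) of 10 gene lists (y axis), 1 point per treatment, filled where camera's adjusted p at the preset correlation was under 0.05. The median of the ATF4 targets was -0.69 with SMZ, 0.21 with TMP, -0.075 with CTX and -0.35 with DMSO.

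The drugs were then compared with each other, at 200 µg/ml of SMZ and 50 µg/ml of TMP or CTX. If the 50 µg/ml of CTX counts both drugs, CTX wells held less TMP and less SMZ than the wells of either drug alone. Differences between CTX and either drug therefore cannot be told apart from a difference in dose. ATF4 targets were higher with TMP than with SMZ in 38 of 39 cases and lower in none. Within the ATF4 target list there were 38 higher and 0 lower adjusted over the list alone, with camera adjusted p = 2.0e-39, and adjusted p = 0.25 with an estimated correlation. CHAC1, which degrades glutathione (chromosome 15, 40952962 to 40956519), was 4.03-fold higher (2.01 ± 0.17, adjusted p = 9.6e-08, edgeR, n = 3 against 3), and DDIT4 (1.16 ± 0.054) and the tRNA synthetase genes GARS1 (1.09 ± 0.067) and CARS1 (1.14 ± 0.072) were higher. Of 36 hypoxia and glycolysis genes 23 were higher and 1 lower, with SLC2A1 at 0.88 ± 0.064 and VEGFA at 0.80 ± 0.061. The hypoxia and glycolysis list had 25 higher and 1 lower adjusted over the list alone, with camera adjusted p = 2.2e-09, and adjusted p = 0.26 with an estimated correlation. Unfolded protein response genes were higher in 19 of 24 cases and lower in 1, with the chaperone HSPA5 at 0.57 ± 0.056. Within the unfolded protein response list there were 19 higher and 1 lower adjusted over the list alone, with camera adjusted p = 7.4e-09, and adjusted p = 0.26 with an estimated correlation. Of 50 mitotic genes 20 were lower and 1 higher, with TACC3 at -0.36 ± 0.045 and HMMR at -0.39 ± 0.069. TACC3 was at 41.21 to 43.39 CPM in control, 40.24 to 43.72 with TMP and 53.77 to 55.01 with SMZ. HMMR was at 52.03 to 59.22, 51.26 to 55.08 and 67.08 to 72.8 CPM. Both differences thus lay in a higher level with SMZ, while TMP overlapped control. The mitotic list had 1 higher and 21 lower adjusted over the list alone, with camera adjusted p = 3.3e-04, and adjusted p = 0.43 with an estimated correlation. In all 6655 genes differed by edgeR, 3496 higher with TMP and 3159 lower. At 2-fold or more the balance turned, with 132 higher and 363 lower, as it did with a stricter filter (3016 higher and 3228 lower), while DESeq2 gave 3466 and 2434. ACTA1 was the furthest above SMZ (2.81 ± 0.17), with SMDT1, a gene of large spread (2.17 ± 0.58), next, whose call was lost without TMP 3 (log2 fold change 0.36, adjusted p = 0.14) and with limma-voom (adjusted p = 0.14). SAMD12 (-1.68 ± 0.20), ATG9B (-1.59 ± 0.14) and SPIRE1 (-1.49 ± 0.18) were the furthest below.

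CTX also stood above SMZ in 36 of 39 ATF4 targets, and below it in none, with DDIT4 at 0.90 ± 0.054, adjusted p = 2.6e-09 (edgeR, n = 3 against 3). The ATF4 target list had 36 higher and 0 lower adjusted over the list alone, with camera adjusted p = 2.8e-27, and adjusted p = 0.17 with an estimated correlation. Of 36 hypoxia and glycolysis genes 31 were higher and none lower, with NDRG1 at 0.86 ± 0.063 and HK2 at 0.81 ± 0.071. Within the hypoxia and glycolysis list there were 31 higher and 1 lower adjusted over the list alone, with camera adjusted p = 8.4e-14, and adjusted p = 0.17 with an estimated correlation. Syncytiotrophoblast genes were higher in 12 of 24 cases and lower in 1, with GH2 at 0.99 ± 0.057, ENDOU at 1.78 ± 0.20 and GCM1 at 0.55 ± 0.061. Within the syncytiotrophoblast list there were 12 higher and 1 lower adjusted over the list alone, with camera adjusted p = 2.0e-05, and adjusted p = 0.17 with an estimated correlation. By edgeR 6357 genes differed, 3357 higher and 3000 lower. At 2-fold or more 165 were higher and 266 lower, and with a stricter filter 3027 and 3079. DXO, a gene of the major histocompatibility complex with one of the largest spreads (2.44 ± 0.57), ACTA1 (1.97 ± 0.18) and CYP4F22 (1.89 ± 0.17) were the furthest above, and IQCN (-1.52 ± 0.17), SPIRE1 (-1.48 ± 0.19) and CORO1A (-1.40 ± 0.19) the furthest below.

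CTX and TMP were both labelled 50 µg/ml, but the labels do not give the TMP content of CTX. Between them, p53 targets were higher with CTX in 16 of 30 cases and lower in 1 (17 higher and 1 lower adjusted over the list alone). CDKN1A (chromosome 6, 36676460 to 36687339) was 1.31-fold higher (0.39 ± 0.046, adjusted p = 6.9e-05, edgeR, n = 3 against 3), with PHLDA3 at 0.39 ± 0.045, DDB2 at 0.35 ± 0.042 and FDXR at 0.32 ± 0.047. With TMP these genes were all below every control library, while with CTX they lay near control. CDKN1A was at 104.99 to 107.5 CPM in control, 85.67 to 92.45 with TMP and 109.72 to 119.01 with CTX. DDB2 was at 84.48 to 86.68, 67.28 to 70.79 and 85.63 to 89.85 CPM. Camera gave the list an adjusted p = 1.0e-14, and its call held with an estimated correlation (adjusted p = 0.010). ATF4 targets were lower with CTX in 27 of 39 cases and higher in 1, with ASNS at -0.84 ± 0.14, TRIB3 at -0.70 ± 0.087 and PCK2 at -0.50 ± 0.069. Within the ATF4 target list there were 1 higher and 32 lower adjusted over the list alone, with camera adjusted p = 4.8e-26, and adjusted p = 0.14 with an estimated correlation. Of 33 histone genes 7 were lower and none higher, with H2BC5 at -0.66 ± 0.10. Within the histone list there were 0 higher and 11 lower adjusted over the list alone, with camera adjusted p = 9.9e-09, and adjusted p = 0.074 with an estimated correlation. H3C4 (-1.45 ± 0.20) and H2AC7 (-1.68 ± 0.23) share 100% and 98% of their exonic bases with another gene. By edgeR 1112 genes differed, 600 higher with CTX and 512 lower, and 64 at least 2-fold, 47 higher and 17 lower. With 1 library fewer the count of 1112 became 675 without TMP 2, 732 without TMP 3, 634 without CTX 1 and 625 without CTX 2, and 1822 with limma-voom. RNH1 (1.35 ± 0.29) and CLCA2 (1.09 ± 0.16) were among the furthest above. RNH1 was among the 1% of genes with the largest spread, and its control libraries, at 10.6 to 44.1 CPM, spanned most of the range of both drugs, with TMP at 18.03 CPM at most and CTX at 35.7 CPM at least. ARHGEF10 (-0.98 ± 0.17, 59.5% of exonic bases shared on its strand) was among the furthest below. CUTA and FRG1 were also among the genes of largest spread, and CUTA lies in the major histocompatibility complex. CUTA (1.58 ± 0.45) lost its call without TMP 2, TMP 3 or CTX 2 (log2 fold change 0.88 to 1.51, adjusted p = 0.33 at most), with a log2 fold change of 0.88 without CTX 2, and its call was also lost with DESeq2 (adjusted p = 0.11). FRG1 (-1.66 ± 0.40) lost its call without TMP 1, TMP 3, CTX 1, CTX 2 or CTX 3 (log2 fold change -1.32 to -1.76, adjusted p = 0.095 at most) and with limma-voom (adjusted p = 0.14).

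The DMSO library differed from control in many of the groups that SMZ lowered. Of 39 ATF4 targets 23 were lower and none higher, with GDF15 at -0.86 ± 0.092, adjusted p = 2.0e-05 (edgeR, 1 library against 3), DDIT4 at -0.67 ± 0.078 and NUPR1 at -0.74 ± 0.10. The ATF4 target list had 0 higher and 27 lower adjusted over the list alone, with camera adjusted p = 5.4e-16, and adjusted p = 0.18 with an estimated correlation. Hypoxia and glycolysis genes were lower in 20 of 36 cases and higher in none, with HK2 at -0.68 ± 0.10 and SLC2A1 at -0.64 ± 0.094. The hypoxia and glycolysis list had 0 higher and 22 lower adjusted over the list alone, with camera adjusted p = 1.5e-12, and adjusted p = 0.16 with an estimated correlation. Of 16 extravillous markers 8 were lower and none higher, with SERPINE1 at -0.86 ± 0.069. The extravillous trophoblast list had 0 higher and 9 lower adjusted over the list alone, with camera adjusted p = 9.8e-07, and adjusted p = 0.16 with an estimated correlation. Cytotrophoblast genes were lower in 11 of 22 cases and higher in 2, with ITGB4 at -0.37 ± 0.065 and GATA3 at -0.40 ± 0.078. Within the cytotrophoblast list there were 3 higher and 12 lower adjusted over the list alone, with camera adjusted p = 2.6e-04, and adjusted p = 0.18 with an estimated correlation. By edgeR 2673 genes differed, 1244 higher and 1429 lower (46.5% higher), and 196 at least 2-fold, 75 higher and 121 lower. With DESeq2 1016 were higher and 1785 lower (36.3% higher). ZNF90 (2.60 ± 0.63), LYSET (2.25 ± 0.41, 22.3% of exonic bases shared on its strand) and PSMB8 (1.93 ± 0.54) were the furthest above control, and LY6K (-1.65 ± 0.32), EDN2 (-1.52 ± 0.21) and EPHA2 (-1.52 ± 0.20) the furthest below. ZNF90, LYSET and PSMB8 were among the 1% of genes with the largest spread between replicates. PSMB8 lies in the major histocompatibility complex and lost its call without control 3 (log2 fold change 1.59, adjusted p = 0.075) and with DESeq2 (adjusted p = 0.14). Of other cell types' markers, 3 of 6 immune genes were lower, with CSF1R at -0.36 ± 0.068 and CD68 at -0.55 ± 0.15, the second lost with DESeq2 (adjusted p = 0.0521) and without a low-count filter (adjusted p = 0.066). Within the immune list there were 0 higher and 4 lower adjusted over the list alone, with camera adjusted p = 0.0047, and adjusted p = 0.15 with an estimated correlation. The immune list was not called without a low-count filter (adjusted p = 0.34). Of 5 endothelial genes 2 were lower, with CDH5 at -0.59 ± 0.077, and none of 9 stromal genes passed over all genes, with a median of -0.027 and a mean of 0.081. Within the endothelial list there were 0 higher and 2 lower adjusted over the list alone, with camera adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation. The stromal list had 1 higher and 2 lower adjusted over the list alone, with camera adjusted p = 0.60, and adjusted p = 0.71 with an estimated correlation.

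Set against the DMSO library in place of untreated cells, ATF4 targets were higher with TMP in 32 of 39 cases and lower in none, with TRIB3 at 1.12 ± 0.13, adjusted p = 1.7e-04 (edgeR, 3 libraries against 1), AARS1 at 0.97 ± 0.12 and DDIT4 at 0.77 ± 0.079. TRIB3 and AARS1 with TMP were also above every control library. DDIT4 was at 316.45 CPM in DMSO, and its 507.64 to 561.83 CPM with TMP overlapped the 488.03 to 524.59 CPM of control. Within the ATF4 target list there were 35 higher and 0 lower adjusted over the list alone, with camera adjusted p = 1.3e-41, and adjusted p = 0.098 with an estimated correlation. With SMZ 10 were lower and none higher, with DDIT4 at -0.39 ± 0.074 and ATF3 at -0.38 ± 0.079, the second not called in a fit of only these libraries (adjusted p = 0.064). GARS1 (-0.42 ± 0.092) lost its call without SMZ 2 (log2 fold change -0.37, adjusted p = 0.0502), and SLC7A5 (-0.41 ± 0.089) in that fit of only these libraries (adjusted p = 0.073). The ATF4 target list had 0 higher and 30 lower adjusted over the list alone, with camera adjusted p = 1.3e-18, and adjusted p = 0.37 with an estimated correlation. CTX had 2 higher and none lower, DDIT4 (0.51 ± 0.078) and GDF15 (0.52 ± 0.091), with 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.8e-21, and adjusted p = 0.19 with an estimated correlation). DDIT4 and GDF15 with CTX were nonetheless below every control library. GDF15 was at 130.57 CPM in DMSO, 182.92 to 192.85 with CTX and 233.6 to 240.43 in control. Of 36 hypoxia and glycolysis genes 1 was higher with CTX, NDRG1 (0.44 ± 0.091), and none lower. NDRG1 was at 393.69 CPM in DMSO, 507.96 to 550.75 with CTX and 581.75 to 631.08 in control. Within the hypoxia and glycolysis list there were 11 higher and 0 lower adjusted over the list alone, with camera adjusted p = 1.9e-11, and adjusted p = 0.19 with an estimated correlation. NDRG1 lost its call without CTX 1 or CTX 2 (log2 fold change 0.42 to 0.43, adjusted p = 0.13 at most). With TMP 3 of 33 histone genes were higher than in DMSO and none lower, with H2BC5 at 0.58 ± 0.14. The histone list had 4 higher and 0 lower adjusted over the list alone, with camera adjusted p = 2.2e-07, and adjusted p = 0.098 with an estimated correlation. Mitotic genes were lower with TMP in 3 of 50 cases and higher in none, with CDK1 at -0.35 ± 0.076. CDK1 was at 83.81 CPM in DMSO, 69.31 to 73.75 in control and 65.59 to 66.68 with TMP. PTTG1 was at 95.15, 77.51 to 78.94 and 73.84 to 76.78 CPM, and BUB1B at 72.76, 62.25 to 64.89 and 57.35 to 60.59 CPM. Since DMSO lay above control and TMP below it, part of each difference rests on the 1 DMSO library. PTTG1 (-0.34 ± 0.092) lost its call without TMP 1, TMP 2 or TMP 3 (log2 fold change -0.33 to -0.36, adjusted p = 0.075 at most), and BUB1B (-0.31 ± 0.079) without TMP 1 (log2 fold change -0.29, adjusted p = 0.067) and in a fit of only these libraries (adjusted p = 0.060). Within the mitotic list there were 0 higher and 6 lower adjusted over the list alone, with camera adjusted p = 1.6e-07, and adjusted p = 0.35 with an estimated correlation.

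By edgeR 781 genes differed between SMZ and DMSO, 275 higher and 506 lower, 1009 between TMP and DMSO, 540 higher and 469 lower, and 70 between CTX and DMSO, 57 higher and 13 lower. At 2-fold or more 50 were higher and 23 lower with SMZ, the reverse of the balance over all calls, 63 and 54 with TMP, and 3 and 2 with CTX. For TMP limma-voom gave 672 higher and 693 lower. With 1 library on one side these tests recover fewer small changes, so the counts are not comparable with those against 3 control libraries. Without SMZ 2 the first count was 475, and without CTX 2 the last was 28. The mitochondrial transfer RNA gene MT-TE was lower than in DMSO with SMZ (-1.27 ± 0.24), TMP (-1.57 ± 0.24) and CTX (-1.77 ± 0.24). It stood at 6.52 CPM in the DMSO library, 2.47 to 3.39 CPM in the control libraries and at most 3.52 CPM in the drug libraries, so these 3 values rest on 1 shared library. ERBB4 was lower with TMP than in DMSO (-1.49 ± 0.21) and FLRT1 higher (2.07 ± 0.36). LYSET was lower (-2.24 ± 0.40) and RBFOX2 higher (1.35 ± 0.25) with TMP, but the TMP libraries lay close to the control range, so both values rest on the 1 DMSO library. LYSET was at 3.36 CPM in DMSO, 0.67 to 0.73 CPM with TMP and 0.61 to 0.81 CPM in control. RBFOX2 was at 17.4 CPM in DMSO, 38.2 to 53.6 CPM with TMP and 35.5 to 52.7 CPM in control, and both genes had some of the largest spreads between replicates. MYL3 (0.83 ± 0.12) and PTGIS (0.90 ± 0.15) were higher with CTX than in DMSO, and averaged 9.82 and 5.39 CPM in control, above their 6.83 and 3.77 CPM with CTX. TSPAN13 was higher (1.29 ± 0.28) and ADGRF2 lower (-1.21 ± 0.22) with SMZ. Among the furthest from DMSO with SMZ, SKIC2, a gene of the major histocompatibility complex with one of the largest spreads (2.32 ± 0.56), lost its call without SMZ 1 (log2 fold change 2.02, adjusted p = 0.064) and with limma-voom (adjusted p = 0.0507). ZACN, at 0.64 CPM in DMSO and 1.08 to 1.43 CPM in control (1.24 ± 0.29), lost its call without SMZ 2 (log2 fold change 1.08, adjusted p = 0.060) and in a fit of only these libraries (adjusted p = 0.059), and LYSET (-1.62 ± 0.39) without SMZ 1 or SMZ 2 (log2 fold change -1.42, adjusted p = 0.081 at most). With CTX, MYEOV (0.69 ± 0.12) lost its call without CTX 2 (log2 fold change 0.68, adjusted p = 0.058) and ZDHHC23 (-0.61 ± 0.11) without CTX 2 or CTX 3 (log2 fold change -0.58 to -0.64, adjusted p = 0.065 at most).

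The last comparison asked how far the responses to the drugs ran together across genes. Log2 fold changes against control correlated at 0.620 for SMZ and TMP, 0.600 for SMZ and CTX and 0.622 for TMP and CTX, over 21392 genes that are not independent replicates. Unchanged groups simulated against the same controls gave 0.508, 0.502 and 0.517 on average. With the DMSO library as reference in place of control the order reversed, with 0.601, 0.578 and 0.757 for the drugs against 0.773, 0.770 and 0.781 for simulated unchanged groups. The covariances were 0.133, 0.103 and 0.0804, against 0.0343, 0.0341 and 0.0341 in the simulations. SMZ and TMP shared 1549 genes called higher and 1713 called lower, where independent lists would share 507.5 and 490.1, and 162 genes were called in opposite directions. All 3 drugs called 188 genes higher and 491 lower, against 5.15 and 12.2 for independent lists. Of these, 4 and 10 changed at least 2-fold with every drug. The controls are only 3 libraries and could not be divided into sets of at least 2, so part of the excess over simulation may come from the shared controls. With the DMSO reference only the correlations were set beside simulations, and they showed no excess. Covariances and shared calls were not. A response particular to 1 drug also lowers a correlation below that of unchanged groups. These correlations therefore cannot show whether a shared response was absent.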

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

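Alternatives added after the data were seen were the reads recovered from the normalized table, the removal of the major histocompatibility complex with the 1% of genes of largest spread, the fit without DMSO, the fit of control and TMP alone with a replicate block, and the DMSO response beside each drug. No named gene or list reversed its direction past the threshold under any setting. With 1 library left out, calls ran from 7987 to 8594 genes for SMZ against control, 3376 to 4431 for TMP, 335 to 552 for CTX, 1791 to 2120 for DMSO, 5518 to 5957 for TMP against SMZ, 5043 to 5803 for CTX against SMZ, 625 to 945 for CTX against TMP, and 475 to 680 for SMZ, 682 to 1122 for TMP and 28 to 56 for CTX against DMSO. Such fits have fewer libraries. A fold of at least 2 left 1148, 425, 21 and 196 genes against control for SMZ, TMP, CTX and DMSO, 495, 431 and 64 between drugs, and 73, 117 and 5 for SMZ, TMP and CTX against DMSO. Without a low-count filter 1179 genes were called for CTX against control, and 1425, 1610 and 592 for SMZ, TMP and CTX against DMSO. Limma-voom called 1436 for CTX against control, 1822 for CTX against TMP and 215 for CTX against DMSO, where DESeq2 called 312. Fits of only the groups compared called 290, 349 and 161 for SMZ, TMP and CTX against DMSO. Without the histocompatibility complex and the genes of largest spread, 154 were called for CTX against DMSO. The cause of these shifts was not tested. All other counts of changed genes under these alternatives stayed within 1.5 times. Against DMSO in place of control the drug responses correlated at 0.601, 0.578 and 0.757, below the 0.773, 0.770 and 0.781 of simulated unchanged groups against 1 library, and the genes called in 1 direction with all 3 drugs went from 679 to 14 at 2-fold. Control and TMP met the rule on the correlation of deviations, and no other groups did: beyond those 3 pairs, SMZ had 1 over 0.1 with control and 1 with TMP, and CTX none. Of 12 libraries 6 correlated best with their own number. With the replicate block on control and TMP alone 5798 genes were called, and no call of a gene or list named for TMP changed. In a fit of all 12 libraries with the replicate block, the p53 list (adjusted p = 0.0509), GGH (adjusted p = 0.059) and ERMARD (adjusted p = 0.058) were not called for CTX against control, nor CUTA (adjusted p = 0.067) for CTX against TMP, and no other named call changed. There 9229, 4700 and 907 genes were called for SMZ, TMP and CTX against control, 6715 and 6393 for TMP and CTX against SMZ, and 1218 for CTX against TMP. Over all single-gene results with 1 library left out, 112 lost their call and 1583 kept their side of the threshold. With an estimated correlation 57 list results lost their call and 9 kept their side. Fry, which tests whether a list moved one way and not against other genes, did not call 8: ATF4 (adjusted p = 0.29), hypoxia (0.070), aryl hydrocarbon receptor (0.070) and stromal (0.054) for CTX against control, ATF4 (0.056) and hypoxia (0.0512) for CTX, ATF4 (0.0515) for SMZ and mitosis (0.081) for TMP against DMSO. Fry called 5 that camera did not: folate (adjusted p = 0.0017), apoptosis (3.3e-04), xenobiotic (1.3e-04) and endothelial (3.6e-04) for SMZ and folate (0.021) for TMP. At these depths 38% of simulated 1.2-fold changes, in genes with a mean of at least 1 CPM, were recovered for SMZ against control. Smaller changes may therefore go unseen (9208 genes were called with other scaling factors).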

Other observations

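The tests of shared controls, of 1 common shift, of library scaling, of copies of the histocompatibility complex, of gene location and of the raw table alone were chosen after the result was seen. A further gene group not yet described was that of Wnt targets, of which 10 were measured. One of its members, MYC, also belongs to lists described above. With SMZ 6 fell and none rose, with TNFRSF19 at -1.27 ± 0.080, adjusted p = 7.3e-10 (edgeR, n = 3 against 3), the cyclin CCND1 at -0.91 ± 0.067 and the feedback inhibitor AXIN2 at -0.79 ± 0.050. The Wnt target list had 0 higher and 6 lower adjusted over the list alone, with camera adjusted p = 0.0010, and adjusted p = 0.14 with an estimated correlation. With TMP 5 fell and 1 rose, with TNFRSF19 at -0.87 ± 0.077, CCND1 at -0.43 ± 0.066, RNF43 at -0.52 ± 0.089 and AXIN2 at -0.28 ± 0.050. RNF43 shares 59.5% of its exonic bases with other genes on its strand. Within the Wnt target list there were 1 higher and 6 lower adjusted over the list alone, with camera adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation. With CTX 5 fell and none rose, with TNFRSF19 at -0.40 ± 0.075. The Wnt target list had 0 higher and 5 lower adjusted over the list alone, with camera adjusted p = 2.3e-04, and adjusted p = 0.15 with an estimated correlation. The CTX call of CCND1 (-0.26 ± 0.066) was lost without control 2, control 3, CTX 1 or CTX 2 (log2 fold change -0.20 to -0.27, adjusted p = 0.13 at most), that of AXIN2 (-0.22 ± 0.050) without control 1 or CTX 3 (log2 fold change -0.20 to -0.21, adjusted p = 0.089 at most) and that of RNF43 (-0.42 ± 0.089) without control 1 or CTX 1 (log2 fold change -0.34 to -0.40, adjusted p = 0.074 at most). In the DMSO library 5 were lower and none higher, with AXIN2 at -0.40 ± 0.072 and MYC at -0.50 ± 0.12. Within the Wnt target list there were 0 higher and 5 lower adjusted over the list alone, with camera adjusted p = 5.3e-04, and adjusted p = 0.16 with an estimated correlation.

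Drug metabolism and cell death genes moved both ways with SMZ. Of 20 genes of xenobiotic metabolism 10 rose and 5 fell, with the epoxide hydrolase EPHX1 at 0.56 ± 0.086, adjusted p = 3.1e-05 (edgeR, n = 3 against 3), MTARC1 at 0.37 ± 0.046, the electron donor POR at -0.48 ± 0.049 and CYB5A at -0.34 ± 0.047. The xenobiotic metabolism list had 10 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.28, and adjusted p = 0.44 with an estimated correlation. Of 29 apoptosis genes 10 rose and 5 fell, with the initiator caspase CASP8 at 0.71 ± 0.067, cytochrome c CYCS at 0.53 ± 0.058, the survival gene BCL2L1 at -0.47 ± 0.046 and the caspase inhibitor CFLAR at -0.36 ± 0.056. The apoptosis list had 10 higher and 5 lower adjusted over the list alone, with camera adjusted p = 0.32, and adjusted p = 0.44 with an estimated correlation.

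The real grouping of the 6 libraries called 9229 genes for SMZ against control, 4625 for TMP, 750 for CTX, 6655 for TMP against SMZ, 6357 for CTX against SMZ and 1112 for CTX against TMP. The highest of the other splits called 0 genes for CTX against SMZ and 1 gene in each of the other comparisons. Of the splits of control and TMP that parted all 3 same-numbered pairs, the real one called 4625 and the highest other 1. In each comparison 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Splits other than the real one put libraries of both groups on each side, so any group difference enters their spread and lowers their calls. Their low counts therefore do not measure what chance alone would call.

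The responses to all 3 drugs resembled that of the DMSO library. Covariances with the DMSO response were 0.145 for SMZ, 0.0854 for TMP and 0.0665 for CTX, and the lowest ratio to the highest simulated value was 1.83. The simulations drew each gene independently, so they lack deviations that genes share within the control libraries. Only under that assumption does the ratio argue against shared controls as the whole cause. A common shift of all treated wells, such as an equal amount of vehicle, would by itself give about the same part of the DMSO change in each drug. That part was 0.383 with CTX (0.360 to 0.417 with 1 library left out), 0.600 with TMP (0.479 to 0.716) and 1.29 with SMZ (1.255 to 1.373). This argues against 1 common shift as the only change. A common shift joined by each drug's own response in the same genes would also give unequal parts, and this test cannot tell. Removing the GC and length trend kept at least 96.9% of the covariance, which argues against that trend. Vehicle in amounts that differed between wells may account for part of the resemblance, as may a real response that the drugs share with DMSO, and the labels give no vehicle content to decide.

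As a list, ATF4 targets were higher with TMP and lower with SMZ, though GDF15, ATF3 and PPP1R15A were below control with both. For the list as a whole, a response of opposite sign to each drug may be the cause. The TMP rise did not rest on 1 library, since the lowest median with any of the 6 left out was 0.151. Nor did scaling set the difference between TMP and SMZ, which lay 0.815 or more above the median of all genes, or GC content and length, after whose removal it was 0.82. A biological cause remains a hypothesis found and tested on the same data, and the list calls were lost with an estimated correlation (adjusted p = 0.25 for TMP against SMZ).

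Some genes jumped between replicates of 1 group, and the 1% with the largest spread (149 genes) included ASNS, RNH1, RBFOX2, LYSET, ZNF90, ERMARD, FRG1, SMDT1, NELFE, ATF6B, CUTA, DXO, PSMB8 and SKIC2. Over every chromosome, they were more frequent than other genes among mitochondrial genes (10 of 147 against 26 of 14250 with a position, odds ratio 39.9, 95% interval 16.8 to 87.4, Fisher's exact test) and in the major histocompatibility complex (10 against 34, odds ratio 30.5, 13.2 to 64.6). Reads divided among other copies of the histocompatibility complex are a candidate cause for the 10 there, and do not explain the mitochondrial 10, for which no cause was tested. Deviations in both deposited tables correlated at a median of 0.999 over the 97 of these genes found in both, which argues against a fault of the raw counting run alone for those 97. Exons shared on the same strand stayed open, with an odds ratio of 0.554 (0.199 to 1.24). No biological explanation was tested, and 28, 18 and 3 of these genes were called for SMZ, TMP and CTX against control.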
